A study of Homo sapiens with 6 samples.

How the data were processed

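Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on Calu-3, an established human airway epithelial line derived from a lung adenocarcinoma. The series holds 6 libraries. There are 2 replicate libraries of EHF (Ets homologous factor, an epithelial transcription factor of the ETS family), 1 of H3K4me1, 1 of H3K27ac and 2 of input DNA. H3K4me1 is a histone modification found at enhancers, and H3K27ac marks active enhancers and promoters. The labels pair the first input with both EHF libraries and the second with both histone libraries. The analysis used the 4 deposited interval lists, and the reads and the input libraries were not analysed here.

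Per the submitters' processing notes, Bowtie 1.0.0 and HOMER 1.2 were used with the genome build hg19. Per the file headers, each library was called separately with HOMER findPeaks, in factor style for EHF and histone style for the marks, so replicates were not pooled. The false discovery rate was set to 0.01. A peak had to reach 4-fold over the input and 4-fold over the surrounding 10 kb, each with a Poisson p of 1e-04. The maximum considered was set to 1 tag per bp. The headers count 0 mark regions removed by the rule on the surroundings. The peak size was estimated by the program for EHF, as 150 bp in replicate 1 and 125 bp in replicate 2. The mark calls started from windows of 500 bp that were stitched into regions of variable length. These settings bear on the measurements. A rule of fold over input and over the surroundings removes broad or weakly enriched signal, stitching sets the width of mark regions, and a peak missing from a list means only that it did not pass the rules.

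The deposited score of each interval is, per the file headers, its normalized tag count: the authors scaled each library to 10000000 tags. The scores are whole numbers. Their sum is 1.02 times the header's tags in peaks after scaling in EHF replicate 1, 1.01 times in replicate 2, and 1.00 times in both mark lists. The score is the authors' value for the interval, with no error of its own, and was used to describe, rank or filter intervals within a list. Scores of shared sites were also correlated between the EHF lists, and scores per kb were compared between parts of the genome within a list. The score is not an enrichment over input, because the lists carry no input tags per interval. Some scores exceed what 1 tag per base on each strand would allow. An H3K27ac region on chromosome 17 reached 2663 per kb, although scaling lowered the counts of that library of 21426939 tags. Such scores therefore count repeated tags at a position, whose share was not examined.

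Depth per the file headers was 10176290 tags in EHF replicate 1, 8418631 in EHF replicate 2, 12989646 in H3K4me1 and 21426939 in H3K27ac. Shares of tags and of intervals are given with exact (Clopper-Pearson) 95% binomial intervals. These cover counting error only, since tags from amplified libraries and neighbouring intervals are not independent. The labels do not say whether the EHF replicates came from separate cultures. Each mark has 1 library, so no comparison that involves a mark has a replicate check of that mark. All p-values below describe positions within these libraries and not the spread between cultures.

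Intervals were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlap meant at least 1 bp in common. An EHF peak of replicate 1 that overlapped a peak of replicate 2 was called a shared EHF site, and its position is the merged span of both peaks. Overlap was tested by a two-sided circular-shift permutation test. All intervals of one list on a chromosome were moved by 1 random offset and wrapped at the furthest interval end seen on that chromosome in any list, in 10000 draws. The smallest p these draws can give is 0.0002. The 10 overlap tests form a family, and Benjamini-Hochberg adjusted values are given. Shared sites were compared with peaks of a single replicate by two-sided Fisher's exact tests, adjusted over 12 tests. Correlations used 100000 permutations and region widths 10000.

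The shift test was tested on simulated data for the comparison of EHF sites with H3K27ac regions. Of 200 sets of 768 random positions, 3.00% passed the 0.05 threshold. These positions were drawn evenly and independently along the chromosomes, so the simulation does not cover sites that cluster as real ones may. With 50% of the positions placed inside H3K27ac regions, all 20 sets passed and the recovered share averaged 49.96%.

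The designs, the gene lists, the motifs and the rule for named items were fixed before the data were examined. A gene table of the assembly GRCh38.p14 was at hand, which is not the build of the interval lists, and coordinates were not converted. Gene names, genomic features, motif content and the 20 fixed gene lists were therefore not analysed here. The rule for this case names the 15 shared EHF sites with the best mean rank of score in both lists and the 10 longest regions of each mark, by position. Coordinates are hg19 and count from 1. Alternatives were a stricter overlap, the part of each list at or above its median score, a shift limited to 1000000 bp, lists without very wide regions, single replicates, merged mark regions and, for the replicate overlap, an equal number of peaks or peaks extended by 200 bp.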

Results

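The study asked where EHF binds in Calu-3 airway epithelial cells and how its binding relates to histone marks of enhancers and promoters. The EHF list of replicate 1 held 1537 peaks and that of replicate 2 held 5216. The H3K4me1 list held 31950 regions covering 23.6 Mb, and the H3K27ac list held 34638 regions covering 64.9 Mb. The median width was 501 bp for H3K4me1 regions and 1370 bp for H3K27ac regions. The share of tags inside called intervals was 0.155% in EHF replicate 1 (95% interval 0.152% to 0.157%) and 0.740% in EHF replicate 2 (0.734% to 0.746%). It was 5.80% in the H3K4me1 library and 28.9% in the H3K27ac library. EHF replicate 2 therefore had more tags in peaks than replicate 1 from a shallower library. The caller had set aside 2953 of 4764 putative peaks (62.0%) against the input in replicate 1, and 2790 of 8248 (33.8%) in replicate 2.

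The first comparison asked which EHF sites recurred between the replicates. In all, 768 EHF sites were found in both lists. They made up 49.97% of the replicate 1 peaks (95% interval 47.4% to 52.5%) and 14.7% of the replicate 2 peaks (13.8% to 15.7%). After circular shifts of replicate 1, on average 0.0601% of its peaks met a replicate 2 peak, an 831-fold difference (two-sided permutation p = 0.0002, adjusted p = 0.0002 over 10 tests, the smallest the draws can give). Shifts limited to 1000000 bp gave a mean of 0.121% and a 415-fold difference, and peaks extended by 200 bp gave a 222-fold difference (p = 0.0002 for both permutation tests). The centres of the paired peaks lay a median of 22 bp apart, and 55.7% of them were within 25 bp of each other. The deposited scores of the shared sites had a median of 10 in replicate 1 and 15 in replicate 2. They were correlated across sites, with a Spearman rho of 0.48 and a Pearson r of 0.61 (permutation p = 1e-05 for both, the smallest 100000 draws can give). Without the 2 sites farthest from the median of replicate 1, r was 0.57. Sites are not independent replicates. Both replicates were called against the same input, so part of the overlap may come from that shared library, which could not be separated with these lists.

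Recurrence depended on the score. Of the 526 replicate 1 peaks with a score of 6 to 8, 27.8% were found in replicate 2 (95% interval 23.97% to 31.8%). Of the 96 with a score of 15 to 19, 93.8% were found (86.9% to 97.7%), as were all 33 peaks with a score of 20 or more (lower limit 89.4%). Among replicate 2 peaks, 5.24% of the 1640 with a score of 6 to 10 were found in replicate 1 (4.22% to 6.44%). This rose to 67.4% of the 132 with a score of 30 or more (58.7% to 75.3%), where a block of chromosome 17 described next is left out.

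**Figure D1:**
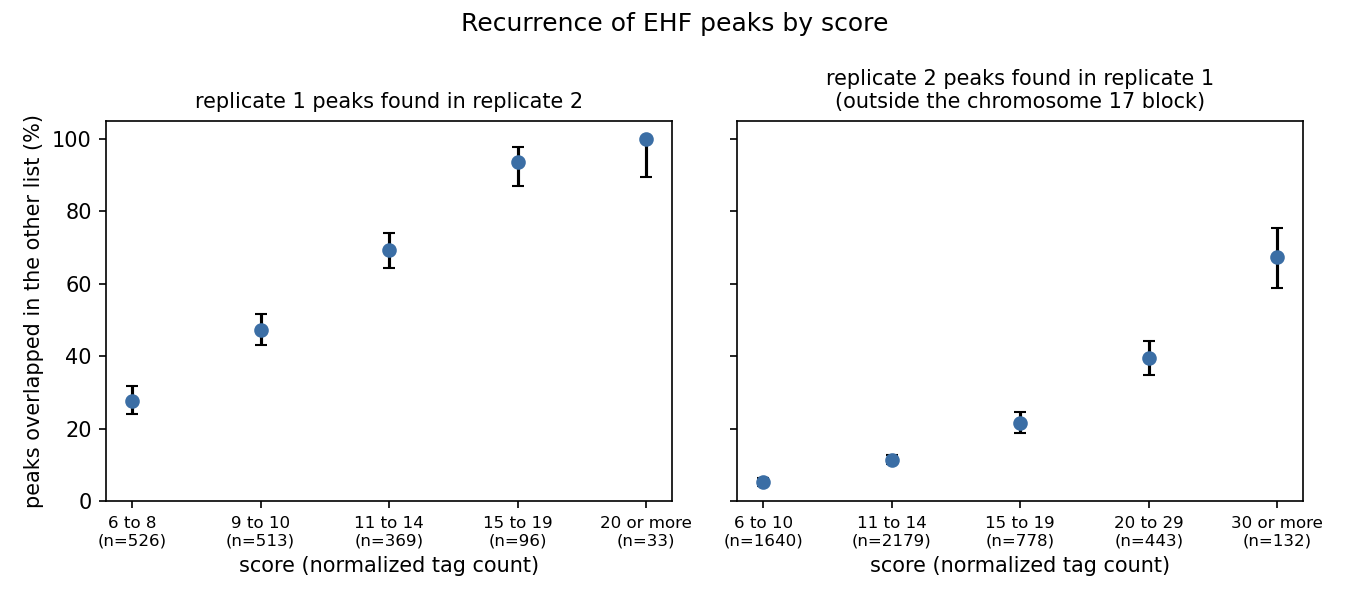
Share of EHF peaks of one replicate (left, replicate 1; right, replicate 2) overlapped by a peak of the other, in percent, by score class; n is the number of peaks, points are shares and bars exact 95% binomial intervals. The share in replicate 1 rises from 27.8% to 100% and that in replicate 2 from 5.24% to 67.4%.

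One stretch of chromosome 17, from 37500001 to 39000000, did not follow this relation. It was delimited after the scores were seen, as the run of 0.5 Mb bins in which the median replicate 2 score was at least 2 times that of the whole list. It held 44 EHF peaks of replicate 2, with scores of up to 693, against at most 84 in the rest of the genome. Of the 20 highest-scoring replicate 2 peaks, 17 lay in it. None of the 44 was found in replicate 1, which had 1 peak in the stretch, with a score of 11. Of the replicate 2 peaks with a score of 24 or more, 0 of 35 inside the stretch recurred, which allows a share of up to 8.57% by the limit of 3 counts and up to 10.003% by the exact 95% interval. Elsewhere 185 of 333 recurred, or 55.6% (95% interval 50.04% to 61.0%; two-sided Fisher's exact test, p = 3.9e-12). The median score per kb of the H3K27ac regions was 318 inside the stretch and 29.9 on the rest of chromosome 17. That of the H3K4me1 regions was 128 inside and 23.6 on the rest. No shared EHF site lay in the stretch, so that the shared set used below does not contain it.

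**Figure D2:**
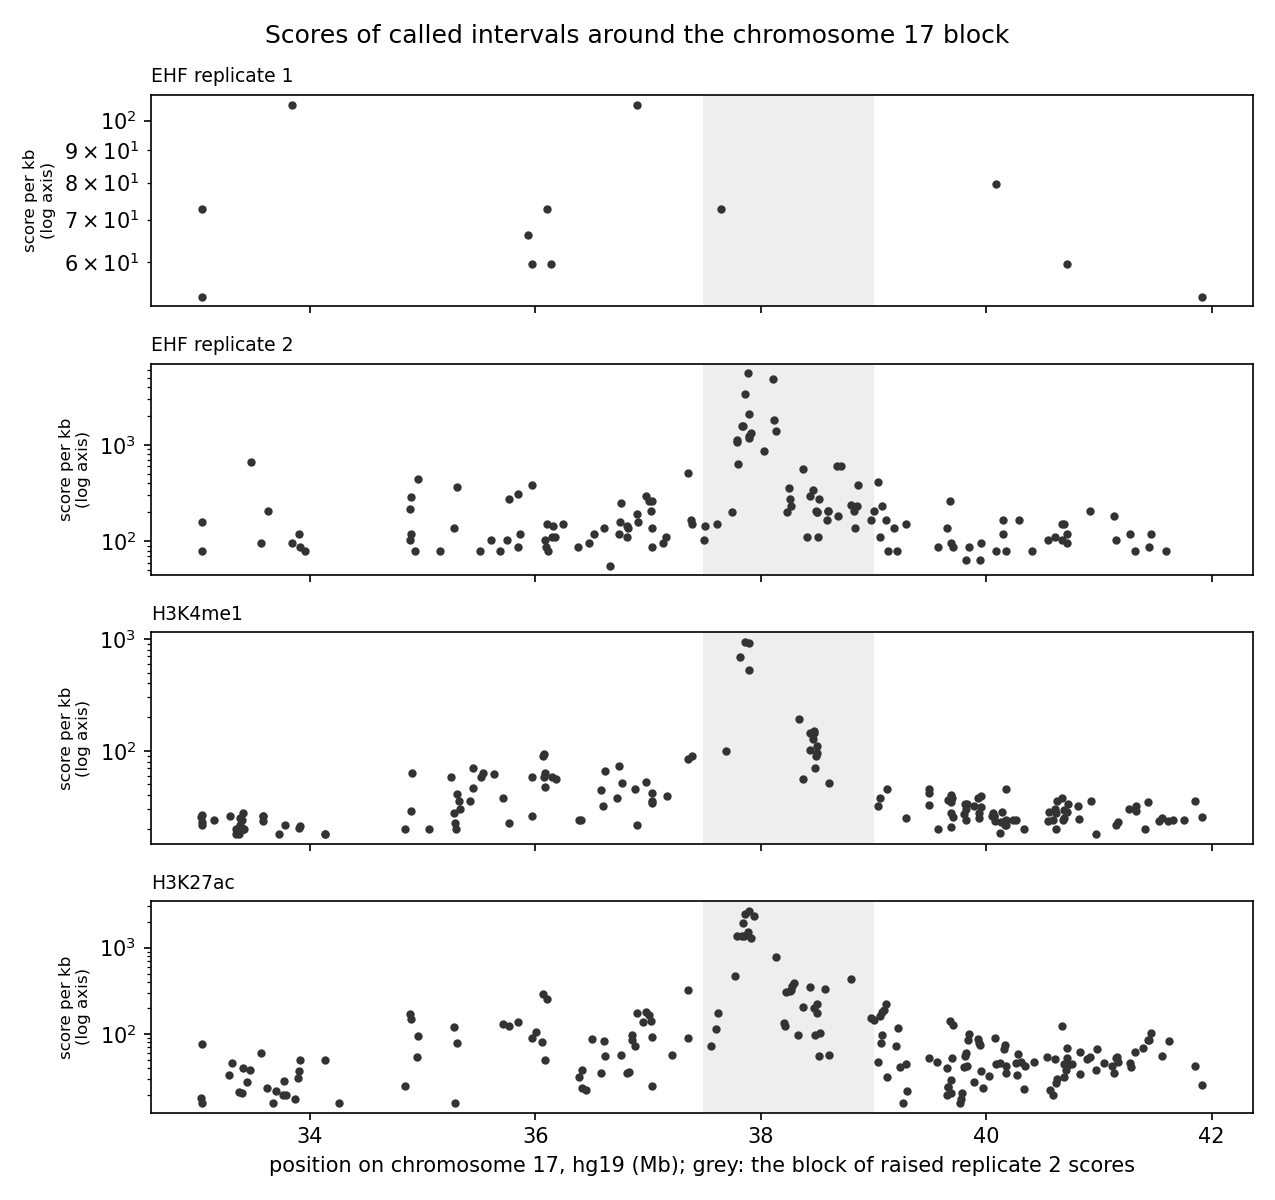
Scores per kb (log axis, with its own scale in each panel) of called intervals against their position on chromosome 17 in Mb (hg19) for EHF replicates 1 and 2, H3K4me1 and H3K27ac; each point is 1 interval and grey marks 37.5 to 39 Mb. Scores rise in the grey stretch in EHF replicate 2 and both marks, whereas EHF replicate 1 has 1 peak there. Some mark regions at lower coordinates outside it are raised too, such as H3K27ac at 36.07 Mb (290 per kb) and at 37.36 Mb (323 per kb).

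The second comparison asked how EHF sites relate to H3K27ac. Most shared EHF sites lay in H3K27ac regions. Of the 768 sites, 597 overlapped one, or 77.7% (95% interval 74.6% to 80.6%), against 2.49% after shifting, a 31.2-fold difference. The share was 60.8% for all replicate 1 peaks and 63.8% for all replicate 2 peaks, 24.8-fold and 25.6-fold above their shifted means. Each of these 3 tests gave a permutation p of 0.0002 (adjusted p = 0.0002). Shifts limited to 1000000 bp, which keep each site in its own part of the chromosome, raised the shifted mean to 4.13% and lowered the difference to 18.8-fold.

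The H3K27ac regions that held a shared EHF site were wider than the others. Their median width was 2669 bp (quartiles 1657 and 4597 bp, 591 regions), against 1353 bp (643 and 2268 bp) in the 34047 regions without one (permutation test of the medians, p = 0.0001, the smallest 10000 draws can give). Per base, however, the density of shared sites varied little above the narrowest class. In 5 width classes of equal number it was, from narrow to wide, 5.18, 8.03, 9.53, 9.70 and 9.51 sites per Mb. A single shared site was found in 585 of the regions and 2 sites in 6 of them. The widest of the 6 was the region at 30278662 to 30312083 on chromosome 20.

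The third comparison asked how EHF sites relate to H3K4me1. Few EHF sites lay inside H3K4me1 regions, although more than after shifting. Of the 768 shared sites, 73 overlapped such a region, or 9.51% (95% interval 7.52% to 11.8%), against 1.11% after shifting, an 8.60-fold difference. The shares were 10.1% for replicate 1 and 7.98% for replicate 2 (permutation p = 0.0002 and adjusted p = 0.0002 for each of the 3). The limited shifts gave a mean of 2.06% and a 4.61-fold difference for the shared sites.

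H3K4me1 regions were instead found beside the EHF sites. Within 500 bp of a shared site the share with an H3K4me1 region was 32.3% (29.0% to 35.7%), and within 2000 bp it was 52.5% (48.9% to 56.1%), against 5.25% after shifting. The centres of 50 sites, or 6.51%, lay in an H3K4me1 region, compared with 14.1% of the points 1000 bp on the side of lower coordinates and 14.8% of those on the other. On the first side 94 sites had the mark only beside them and 36 only at the centre, and on the second side the counts were 101 and 37 (two-sided exact McNemar tests, p = 3.7e-07 and p = 4.8e-08). No such dip was seen in the called H3K27ac regions. They covered 75.1% of the centres, 47.9% and 47.8% of the points at 1000 bp, and 11.8% and 13.4% of the points at 5000 bp. Stitching of 500 bp windows, which gave H3K27ac regions a median width of 1370 bp, can hide a narrow dip. Tags at the sites were not examined, so the region lists cannot tell whether the H3K27ac signal itself dips.

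**Figure D3:**
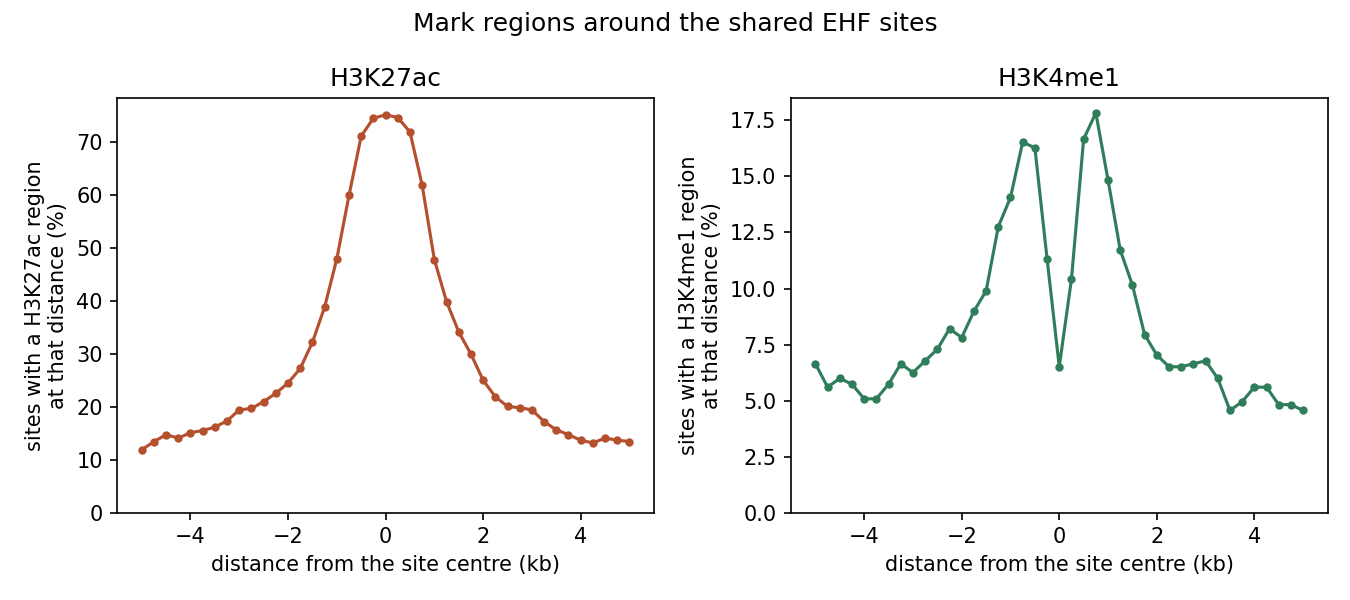
Share of the 768 shared EHF sites, in percent, with an H3K27ac region (left) or an H3K4me1 region (right) at each distance from the site centre in kb, in steps of 250 bp; the 2 vertical axes differ in scale. H3K27ac is highest at the centre (75.1%), whereas H3K4me1 falls to 6.51% at the centre and reaches 17.8% beside it.

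By both marks together, 537 of the shared sites (69.9%) lay in H3K27ac regions alone and 60 (7.81%) in both marks. A further 13 (1.69%) lay in H3K4me1 regions alone and 158 (20.6%, 95% interval 17.8% to 23.6%) in neither. Peaks seen in a single replicate were less often in H3K27ac regions. The share was 44.0% of the 769 peaks found only in replicate 1, which is 33.8 percentage points below the shared sites (Fisher's exact test, adjusted p = 1.2e-41). It was 61.6% of the 4448 peaks found only in replicate 2, 16.2 points below (Fisher's exact test, adjusted p = 2.6e-18). Part of this went with the score: among replicate 2 peaks with scores of 12 to 23 the difference was 6.14 points (75.2% against 69.0%, Fisher's exact test, unadjusted p = 0.013). The shares in H3K4me1 regions were 9.51% for shared sites, 10.9% for replicate 1 alone and 7.87% for replicate 2 alone, and neither difference passed Fisher's exact test (adjusted p = 0.44 and p = 0.17). In the same order, the shares in H3K4me1 without H3K27ac were 1.69%, 3.90% and 2.54% (Fisher's exact tests, adjusted p = 0.018 and p = 0.24). Those in both marks were 7.81%, 7.02% and 5.33% (Fisher's exact tests, adjusted p = 0.56 and p = 0.015). These split shares also carry the difference in H3K27ac. H3K4me1 was then compared separately inside and outside H3K27ac regions, in 4 tests chosen after these results were seen. Inside, it was found at 60 of 597 shared sites (10.1%) and 54 of 338 peaks of replicate 1 alone (16.0%), a lower share at shared sites (Fisher's exact test, adjusted p = 0.037 over the 4 tests). The other 3 comparisons did not pass. They were 8.66% of the 2738 peaks of replicate 2 alone inside (Fisher's exact test, adjusted p = 0.6), and outside 7.60% of 171 shared sites against 6.96% of 431 and 6.61% of 1710 peaks (Fisher's exact tests, adjusted p = 0.86 and p = 0.84).

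The 15 shared EHF sites with the best mean rank of score had scores of 18 to 45 in replicate 1 and 39 to 84 in replicate 2. Chromosomes 3 and 20 held 4 each and chromosome 8 held 3. Of the 15, 12 overlapped an H3K27ac region, 2 overlapped an H3K4me1 region, and 12 had an H3K4me1 region within 2000 bp of the centre. The first, at 32191941 to 32192091 on chromosome 8, had scores of 45 and 84, and its nearest H3K27ac region was 62104 bp away. The second, at 58406118 to 58406268 on chromosome 20, had scores of 28 and 76. It lay in an H3K27ac region of 7915 bp, and an H3K4me1 region lay 267 bp from its centre. The third, at 170720015 to 170720165 on chromosome 3, scored 28 and 52 and lay in an H3K27ac region of 6466 bp. The fourth, at 185255287 to 185255456 on chromosome 3, scored 30 and 49 and lay in an H3K27ac region of 2605 bp. The site at 193561726 to 193561876 on chromosome 3 scored 20 and 49, in an H3K27ac region of 7197 bp. The site at 177246402 to 177246555 on chromosome 3 scored 20 and 45 and was covered by both marks. The other site that overlapped H3K4me1, at 37749531 to 37749690 on chromosome 8, scored 27 and 46. The sites outside H3K27ac also included one at 30865336 to 30865486 on chromosome 20, with scores of 23 and 51 and an H3K27ac region 11378 bp away. The third such site, at 30764271 to 30764421 on chromosome 18, scored 24 and 44 and its centre lay 218 bp from an H3K27ac region. What genes lie at these positions was not analysed here.

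The fourth comparison asked how far the mark lists coincide. Of the H3K4me1 regions, 14431 (45.2%, 95% interval 44.6% to 45.7%) overlapped an H3K27ac region, 14.4-fold above the 3.14% after shifting. Of the H3K27ac regions, 11949 (34.5%, 34.0% to 35.0%) overlapped an H3K4me1 region, 12.9-fold above the 2.68% after shifting (permutation p = 0.0002 and adjusted p = 0.0002 for both). With shifts limited to 1000000 bp the mean for H3K27ac regions was 4.19% and the difference 8.24-fold. By bases, 9.94 Mb carried both marks, which is 42.1% of the H3K4me1 and 15.3% of the H3K27ac coverage. The share of H3K27ac regions with H3K4me1 was 21.7% in the narrowest of the 5 width classes and 60.5% in the widest, and the centre of the region was itself in H3K4me1 in 14.7% of all H3K27ac regions. A wider region has more room to meet a mark by 1 bp, and by bases the share of H3K27ac in H3K4me1 did not rise with width. From narrow to wide it was 17.1%, 17.4%, 12.4%, 13.5% and 16.4%.

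The 10 longest H3K27ac regions were 30244 to 44049 bp wide. The longest, at 96859812 to 96903860 on chromosome 15, held no H3K4me1 region and no EHF peak. The next, at 54781360 to 54819099 on chromosome 2, held 7 H3K4me1 regions and 2 EHF peaks of replicate 2. Of the 10, 7 held H3K4me1 and 3 held a shared EHF site. These 3 were at 46661249 to 46698396 on chromosome 17, at 30278662 to 30312083 on chromosome 20, which held 2 shared sites and 6 H3K4me1 regions, and at 56258787 to 56290172 on chromosome 20, which held 9 EHF peaks of replicate 2, 1 of them shared. The 10 longest H3K4me1 regions were 5491 to 9467 bp wide, led by the region at 36753555 to 36763021 on chromosome 22. All 10 overlapped an H3K27ac region, and 1 of them, at 81614296 to 81619786 on chromosome 16, held a shared EHF site.

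**Figure D4:**
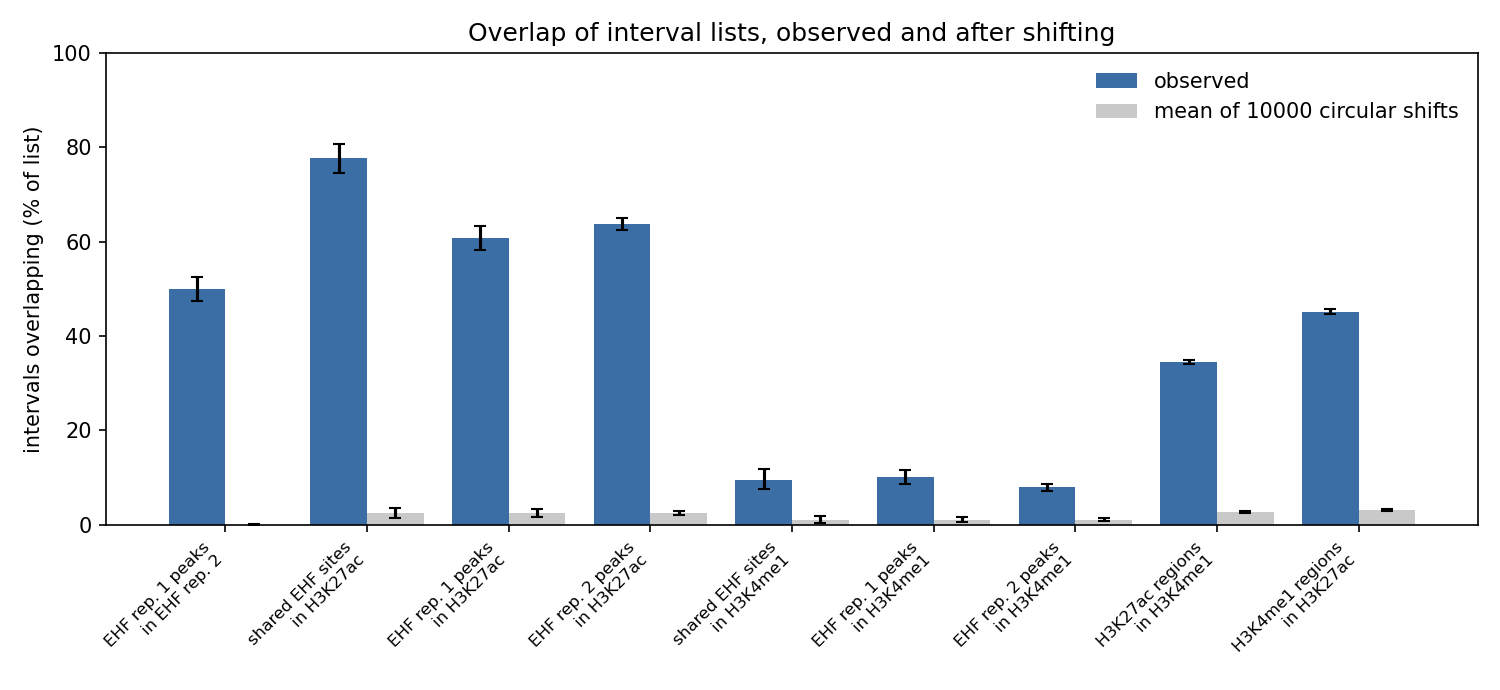
Share of each list, in percent, overlapping another list by at least 1 bp: observed (blue, with exact 95% binomial intervals) and the mean of 10000 circular shifts (grey, with the central 95% of the shifts). The shared EHF sites reach 77.7% in H3K27ac and 9.51% in H3K4me1, each above its shifted range.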

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

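Each overlap stayed above its shifted mean, with a permutation p of 0.0002, under every alternative that was run. Of the 54 alternative values in all, 50 were classed as unchanged. For tested results this meant the same direction and the same side of the 0.05 threshold, also where neither value passed it. The counts of named sites have no test and were classed by their size. Some alternatives could not change a value, such as leaving out the chromosome 17 stretch for the score correlation. The alternatives without the chromosome 17 stretch and with replicate 2 scores limited to 12 to 23 were chosen after seeing the data. The replicate overlap ranged from 29.9%, with replicate 2 limited to as many top peaks as replicate 1, to 51.5% with peaks extended by 200 bp, and the difference from shifting ranged from 222-fold with extended peaks to 1674-fold by peak centre. The share of EHF sites in H3K27ac ranged from 60.8% with replicate 1 alone to 78.0% with regions merged across gaps of up to 1000 bp, which left 32371 regions. The share in H3K4me1 ranged from 6.51% by site centre to 13.02% with merged regions. The share of H3K27ac regions in H3K4me1 ranged from 14.7%, by region centre, to 34.5%, and the difference from 8.24-fold with limited shifts to 17.8-fold by region centre. Without replicate 1 or without replicate 2, the EHF shares were 63.8% and 60.8% in H3K27ac and 7.98% and 10.1% in H3K4me1. The higher share of shared sites than of replicate 2 peaks alone in H3K27ac was 6.14 to 16.2 points. For H3K4me1 that difference, which passed no test, turned from 1.64 to -0.81 points with both classes limited to scores of 12 to 23 (Fisher's exact test, p = 0.64). Scores were not matched within that range, and the cause was not tested. Against replicate 1 alone the H3K4me1 difference of -1.42 points became -3.11 points and passed the unadjusted threshold when judged by the site centre (Fisher's exact test, p = 0.031). The number of named sites in H3K4me1 fell from 2 to 1 by centre or by 50% of the shorter interval. Alternatives that need an hg19 annotation or sequence were not run. In EHF replicate 1, where 0.155% of tags lay in peaks, low-scoring sites of replicate 2 were detected less often than high-scoring ones, at 5.24% of those with scores of 6 to 10 and 11.5% of those with 11 to 14. No paired analysis was possible because the labels give replicate numbers to the EHF libraries alone and no fit between groups of replicates was made.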

Other observations

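The tests of the chromosome 17 stretch, of the chromosomes and of gaps in mark regions were chosen after the results were seen. Those of H3K4me1 beside the site centres were written down earlier.

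EHF sites were unevenly spread over the chromosomes relative to H3K27ac. Chromosome 20 held 5.40 shared EHF sites per 100 H3K27ac regions and chromosome 3 held 3.799. Chromosome 3 had 14.4% of the replicate 1 peaks, 12.0% of the replicate 2 peaks, 9.01% of the H3K4me1 regions and 7.07% of the H3K27ac regions. The odds of a shared site against an H3K27ac region were 2.52 times those elsewhere on chromosome 20 and 1.81 times on chromosome 3 (Fisher's exact tests, adjusted p = 6.4e-06 and p = 9.9e-06 over 23 chromosomes). They were also higher on chromosomes 16 (1.62, adjusted p = 0.02) and 15 (1.57, adjusted p = 0.046) by these exact tests. By the same exact tests they were lower on chromosomes 4 (0.362, adjusted p = 5.4e-05), 6 (0.482, adjusted p = 0.0008), 9 (0.401, adjusted p = 0.0023), X (0.348, adjusted p = 0.0026), 21 (0.106, adjusted p = 0.0066) and 13 (0.382, adjusted p = 0.031). Chromosome 21 held 1 shared site and chromosome 13 held 6. The 158 shared sites outside both marks had median scores of 11 and 14 in replicates 1 and 2, next to 10 and 17 for the 597 sites in H3K27ac. A pair of replicate 2 peaks on chromosome 21, at 9825538 to 9825662 and at 9826016 to 9826140, had scores of 67 and 73 and lay in neither an H3K27ac region nor a replicate 1 peak. No intervals were filtered here by position as prone to false signal, and whether this pair reflects binding was not tested.

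A candidate explanation for the uneven spread is the number of copies of each chromosome, or of parts of it, in these cells. More copies give more tags per site and let more sites pass the caller. Within chromosomes the spread was uneven too. Most shared sites of chromosome 3 lay beyond 133662471, of a span of 197.7 Mb. On chromosome 20, of 62.9 Mb, most lay beyond 30292530. H3K27ac regions were not compared by part of a chromosome, so the values below hold for whole chromosomes only. It predicts that EHF peaks per 100 H3K27ac regions rise with the median H3K27ac score per kb of the chromosome. More copies would also let more H3K27ac regions pass, so the prediction holds only if EHF peaks gain more. For replicate 2 the Spearman rho over 23 chromosomes was 0.916 and the Pearson r 0.82 (permutation p = 1e-05 for both, adjusted p = 2.7e-05 and p = 1.3e-05 over 8 relations). Without the 2 chromosomes farthest from the median, r was 0.78. For replicate 1 rho was 0.66 and r 0.68 (p = 0.00098 and p = 0.00057, adjusted p = 0.0011 and p = 0.00057), with r at 0.59 without the 2 farthest. The relation was not particular to EHF. H3K4me1 regions per 100 H3K27ac regions rose with the same score, with rho at 0.64 and r at 0.79 (permutation tests, adjusted p = 0.0012 and p = 1.3e-05), and r at 0.69 without the 2 farthest. Both measures use the H3K27ac list, since the number of regions is the divisor and their scores give the median. A chromosome with many weak H3K27ac regions would be low in both. With the median H3K4me1 score per kb instead, rho was 0.89 for replicate 2 and 0.78 for replicate 1, still with that divisor. Copy number itself was not measured here. A difference between chromosomes in regulatory activity, which was not tested, would give the same relation, so these explanations stay open.

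The strongest EHF peaks of replicate 2, on chromosome 17 between 37.5 and 39 Mb, were missing from replicate 1. Extra copies of the stretch would raise the scores, and the median score per kb was 5.43 times that of the rest of chromosome 17 for H3K4me1 (bootstrap 95% interval 4.08 to 8.15) and 10.6 times for H3K27ac (5.95 to 14.7; permutation p = 1e-05 for both). It was 2.73 times for EHF replicate 2 (284 against 104, bootstrap 95% interval 2.08 to 6.15), whose scores were used to delimit the stretch. For EHF replicate 1 it was 1.22 times (72.8 against 59.6), from 1 peak, which decides nothing. Calu-3 is known to carry an amplification of ERBB2, a receptor tyrosine kinase gene on chromosome 17, so a scaled-up copy number may account for the height of these scores, without showing stronger binding. Why replicate 1 lacks them stays open. Peaks of a score of 24 or more recurred in 55.6% of cases elsewhere and in 0 of 35 there (Fisher's exact test, p = 3.9e-12), but if extra copies raise the scores, peaks of like score are not of like enrichment. The scores of the stretch were therefore divided by 8 factors from 1 to 40, and the chance that none of the 44 peaks recurs was computed from the shares elsewhere by score class, with peaks taken as independent. It was 3.2e-16 without division and 2.7e-09, 1.5e-06 and 0.0022 at the ratios of EHF replicate 2, H3K4me1 and H3K27ac. At the upper limits of the mark ratios it was 0.00025 and 0.019. Of the 2 factors chosen by hand, 20 gave 0.033 and 40 gave 0.55. If a single factor held for all 44 peaks, lower enrichment of replicate 1 would need one above the median ratios of the whole stretch and their limits. The stretch was not even, however, since single regions in it reached 2663 per kb for H3K27ac and 937 per kb for H3K4me1. A larger factor may thus apply to part of the peaks, and the division cannot decide the question. The bootstrap intervals and permutation tests above took neighbouring regions of 1 stretch as independent. They therefore do not measure the uncertainty of its ratios, and the limits are no firm bounds. The share of repeated tags in these scores was not examined. Lower enrichment is not excluded, since the division and the independence of neighbouring peaks are assumptions. The rule of 4-fold over an input that also holds the extra copies could have removed such peaks from replicate 1, but the 2953 peaks set aside against the input have no positions in the lists. The same rule and input were used for replicate 2, whose 44 peaks passed, so the rule alone would not set the replicates apart. A difference between the cells used was not tested.

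H3K4me1 was lower at the EHF site centres than beside them. Uniform under-calling of a weakly enriched mark as the whole reason for the low share at the centres is argued against, since it would lower both places alike and the share 1000 bp away was 2.22 times that at the centre (bootstrap 95% interval 1.70 to 2.99). For the 577 sites with their centre in H3K27ac the ratio was 2.60 (1.95 to 3.69), and 1000 sets of positions at the same relative place in width-matched H3K27ac regions with no EHF peak gave 0.899 (central 95% 0.692 to 1.18). Those positions are not anchored on any gap, so a dip elsewhere in these regions would be averaged away, and the bound set in advance on this ratio cannot exclude a dip common to H3K27ac regions. A search for H3K4me1 on both sides of a gap of up to 2000 bp found one in 30.9% of the 353 regions with a shared site and H3K4me1 (95% interval 26.1% to 36.0%) and in 24.4% of matched regions without EHF peaks (20.4% to 28.6%), which leaves open whether the gap goes with EHF. Open chromatin without nucleosomes at the bound site, or promoters, which carry little H3K4me1 at their centre, may each give this shape, and neither was tested.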
